A study of Mus musculus with 4 samples.

How the data were processed

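Single-cell RNA was measured in 4 libraries from subcutaneous tumours of CT26 cells, a mouse colon carcinoma line that grows in BALB/c mice. Per the labels, 500000 cells carrying a control guide (sgControl) or a guide against Cdk10 (sgCdk10) were injected into 6-week-old female mice with an intact immune system. Tumours were taken on day 14, digested with collagenase II and cleared of red cells by lysis, and the libraries were sequenced on a DNBSEQ-T7. There were 2 libraries per group, taken from the sample titles. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these samples, which can be technical. Within each group the summed counts of the 2 libraries differed by a chi-square per degree of freedom of 52.6 and 42.7 in CT26-like cells. It was 4.10 and 8.60 in macrophage/monocyte-like, 4.39 and 2.76 in neutrophil-like, 1.54 and 1.99 in NK-like and 1.62 and 1.50 in CD4 T-like cells. This measure grows with counts, of which CT26-like cells had far more. The biological coefficient of variation was 0.134, 0.147, 0.268, 0.0965 and 0.125 in the same order. The chi-square values therefore do not rank the classes by spread between libraries. Each library was counted as 1 sample, and these values do not tell separate animals from repeat libraries of 1 tumour.

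The deposited files held raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, as whole numbers with no normalization. The capture kit, aligner, counting software, genome build and strand setting are not given in the sources used here. Gene symbols and Ensembl identifiers were used as the deposited files pair them, and 32158 of the 32285 identifiers were found in the GENCODE M21 annotation. Because the build is not given, no coordinates are printed. In that annotation 37 of the 116 named genes, Cdk10 among them, overlap another listed gene, and reads in the overlap could have been assigned to either. In all 4 libraries together 8453 genes (26.2%) were listed at 0, B2m and Cxcl10 among them. Of protein-coding genes, 15.8% of the 6991 overlapped and 16.0% of the 14634 not overlapped were at 0, so overlap does not account for these zeros as a set. Why B2m and Cxcl10 were at 0 is not known. Neither could be tested, and their 0 is not read as absent expression.

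The sgControl_1 library held 17139 barcodes and 126115602 UMIs, and sgControl_2 held 26728 barcodes and 109098342 UMIs. The sgCdk10_1 library held 25032 barcodes and 101350153 UMIs, and sgCdk10_2 held 18044 barcodes and 117870477 UMIs. Median UMIs per barcode were 6816 and 2742.5 in sgControl and 3218 and 5274.5 in sgCdk10, with a minimum of 500 in each library. Median genes per barcode were 3028, 1657, 1801 and 2510 in the same order. Depth per cell therefore differed more within each group than between the groups.

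Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept, which left 17126, 26720, 25030 and 18037 cells. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold marked 0, 1, 0 and 2 cells, which is too few to have worked, so cells at or above the score that marks about 6% of each library were removed instead (1126, 1676, 1600 and 1105 cells). Of the remaining 81406 cells, 44133 were placed in a named class. Cells were clustered jointly on 3000 variable genes, 40 principal components and 20 nearest neighbours with the Leiden algorithm at resolution 1.0 and seed 1, with no batch correction, into 29 clusters, 24 of them with at least 10 cells. Clusters 12, 13, 15, 16 and 18 to 23, led by immune genes, were clustered again by themselves with the same settings into 22 subclusters, from which the immune-like classes were named. Software was python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

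Clusters were named from 20 marker sets. Names end in "-like" because they rest on these markers alone. The CT26-like class joined clusters 2, 4, 5, 7, 8, 10, 11 and 17 and was named from Tm4sf1, Krt20, Areg, Krt18 and Krt8, which lay 34.7-, 35.6-, 13.9-, 38.8- and 9.06-fold above the macrophage/monocyte-like class. Other epithelial markers did not support the name: Epcam lay at 0.135-fold and Lgals4 at 1.09-fold of that class, and Krt19, Krt7, Cldn3, Cldn4 and Cldn7 had 50, 42, 5, 9 and 23 UMIs in all. The class also carried the fibroblast markers Col1a1, Col1a2, Pdgfra and Col6a1, at 35.8-, 28.1-, 35.1- and 37.4-fold, so these markers alone do not rule out fibroblasts in it. Its clusters were led by histone genes (2 and 7), mitosis genes (4), Krt20 (5 and 8), Areg (10), interferon-induced genes (11) or heat shock and hypoxia genes (17). Clusters 2 and 5 held 35.9% and 30.5% of the class in sgControl_1 and 29.2% and 22.3% in sgControl_2. Clusters 7 and 8 held 20.4% and 26.4% in sgCdk10_1 and 27.8% and 23.8% in sgCdk10_2. The largest clusters of the class therefore differ between the groups. Clusters 2 and 7 share histone genes, 5 and 8 are both high in Krt20, and no batch correction was made. The split between clusters 2 and 7 and between 5 and 8 therefore does not show that the make-up of cell states changed.

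Some clusters were kept out of every class by rules set after the clusters had been seen. Low-RNA clusters (0, 1, 3 and 14) held 26.3% and 45.2% of the cells in sgControl and 31.8% and 21.9% in sgCdk10. Clusters with high matrix genes and no Ptprc (6 and 9), whose leading genes include Dcn, Col6a1 or Col3a1, held 11.5% and 15.3% in sgControl and 9.73% and 9.19% in sgCdk10. Both sets carried the CT26 marker Tm4sf1 near its level in the CT26-like class (626, 774, 926 and 902 CPM), at 575, 841, 994 and 893 CPM in the matrix-high and 458, 590, 781 and 717 CPM in the low-RNA clusters. Cdk10 was lower in sgCdk10 in both, at 22.9, 23.6, 11 and 9.96 CPM and at 23.7, 18.2, 9.33 and 7.94 CPM. Def8 in the matrix-high clusters was at 28428, 37841, 33272 and 29499 CPM, against 2043 to 3642 CPM in macrophage/monocyte-like cells. Ptprc was at 0.15, 3.28, 4.42 and 4.33 CPM in the matrix-high and 17.7, 69.7, 103 and 180 CPM in the low-RNA clusters. The guide was carried by the injected cells, so these values argue against host cells as the main content of the matrix-high clusters. In the low-RNA clusters leukocyte RNA is mixed in, and tumour cells are not ruled out. The CT26-like share is the share of the named clusters alone. Clusters that mixed tumour and immune genes held 0.59%, 2.36%, 3.02% and 3.43% of the kept cells before doublets were removed, and unnamed immune clusters 0.0563%, 0.415%, 0.324% and 1.04%. No fibroblast-like, endothelial-like, pericyte-like, plasma-like, mast-like or gamma-delta T-like class was found. Assigning each cell by its marker score instead gave the cluster's class for 55.0% of the cells, with 48.2% in the CT26-like, 90.5% in the macrophage/monocyte-like, 96.4% in the NK-like, 85.3% in the CD8 T-like and 39.1% in the CD4 T-like class. The score puts every cell into 1 of the named classes and leaves none out. CT26-like and unnamed cells therefore enter the immune-like classes, so refits by this score do not test the immune-like results cleanly.

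UMIs were summed per class and library and tested across libraries, since cells are not replicates. Genes were tested with edgeR's quasi-likelihood test (filterByExpr, TMM scaling, glmQLFit and glmQLFTest), sgCdk10 against sgControl, with Benjamini-Hochberg adjustment within each class. SE is the log2 fold change divided by the square root of F, in absolute value. A class was tested where each library had at least 20 of its cells, which left out genes of the CD8 T-like, regulatory T-like, dendritic-like and B-like classes. Cell numbers per class were tested with edgeR in the same way, with all kept singlets as the total. The difference between the effects in CT26-like and macrophage/monocyte-like cells was tested as an interaction term in edgeR. An exact two-sided permutation test of 2 libraries against 2 cannot go below 0.33 and was not used.

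There were 23 gene lists, tested where at least 3 members passed the filter. They were tested with camera in limma at its preset correlation of 0.01, again with the correlation estimated per list, and with fry, each with Benjamini-Hochberg adjustment over the 52 tests. Genes were named by a rule. Per class, among genes with an adjusted p under 0.05, a mean log2 CPM of at least 4 and every sgCdk10 library on the same side of every sgControl library, the largest rises and falls were taken. The numbers were 12 of each in the CT26-like, 10 in the macrophage/monocyte-like, 8 in the CD8 T-like and 3 in each other class. Gene models without a name, mitochondrial, ribosomal and haemoglobin genes, and receptor variable segments were not named. Per list, up to 3 called members with the largest change were added, or the member with the smallest p where none was called, and a fixed set of sensor, antigen presentation and immune genes was always given. Some genes that this rule would name are not reported here. Groups, tests, markers, lists, the naming rule and most alternatives were fixed before the data were examined.

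Scripts were tested on simulated counts with 200 genes changed. At 2-fold and 4-fold the test recovered 62.1% and 96.9% of them in the CT26-like class (15511 genes) and 57.9% and 89.6% in the macrophage/monocyte-like class (10087 genes). In the NK-like class it recovered 43.0% and 97.8% (6956 genes), in the CD4 T-like class 33.7% and 94.0% (5697 genes), and in the neutrophil-like class 7.78% and 66.7% (1345 genes). False calls numbered 11, 5, 6, 8 and 4 in the same order. Alternatives fixed in advance were RLE scaling, DESeq2, no filter on low counts, the replicate number as a block, each library left out, stricter cells (500 genes, 10% mitochondrial), doublets kept, classes by marker score, equal cell numbers and other totals for the shares. Added after seeing the data were the CT26-like class with the matrix-high or the low-RNA clusters or without the interferon-led cluster, a crossed pairing for neutrophil-like cells, and shares over named cells or cells with at least 1000 UMIs. CPM means UMIs per 1e6 UMIs of the class in that library, with TMM-scaled totals for genes of a tested class other than Cdk10 and with plain totals for Cdk10, genes of classes not tested, and Ptprc, C1qa, Spp1, Hmga2, Tm4sf1 and Def8 levels used as background. Intervals are 95% and, like limits from a count of 0 (3 counts), cover counting error only.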

Results

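The study asks, by its title, how the kinase CDK10 relates to tumour immunity that runs through sensors of nucleic acids. CT26 tumours grown in mice from control cells (sgControl) or from cells with a guide against Cdk10 (sgCdk10) were compared 14 days after injection, with 2 single-cell RNA libraries per group. Libraries held 101350153 to 126115602 UMIs and 16000, 25044, 23430 and 16932 cells after filtering, in the order sgControl_1, sgControl_2, sgCdk10_1 and sgCdk10_2, an order kept wherever 4 values follow. Fold changes are sgCdk10 over sgControl on the log2 scale, ± SE from edgeR, with n = 2 libraries per group.

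Cdk10 (ENSMUSG00000033862), the targeted gene, encodes a cyclin-dependent kinase. In CT26-like cells it was at 23.5 and 22.4 CPM in sgControl and 9.38 and 8.66 CPM in sgCdk10 (95% intervals 22.5 to 24.5, 21.2 to 23.7, 8.66 to 10.2 and 8.03 to 9.33), from 2128, 1283, 612 and 693 UMIs. It fell by 1.32 ± 0.10 (adjusted p = 0.0218, edgeR with Benjamini-Hochberg). In the macrophage/monocyte-like cells of the host it was at 15.9, 5.40, 8.17 and 10.8 CPM, from 14, 8, 29 and 50 UMIs, a log2 fold change of 0.03 ± 0.49 (adjusted p = 0.991, edgeR with Benjamini-Hochberg). Over all immune-like classes together the values were 13.8, 8.87, 7.10 and 8.73 CPM (log2 fold change -0.39 ± 0.38, not tested across genes). In the other classes Cdk10 had few UMIs, with 2, 4, 2 and 18 in NK-like, 0, 7, 6 and 2 in CD4 T-like, 0, 1, 0 and 0 in neutrophil-like and 0, 1, 1 and 11 in CD8 T-like cells. Regulatory T-like cells had 0, 2, 0 and 2, dendritic-like cells 0, 2, 1 and 1, and B-like cells 1, 0 and 0 in the 3 libraries that held them. The position of the guide is not given in the sources used here, so the lower RNA level checks the labels but not the loss of protein. Without sgCdk10_2 the change of Cdk10 expression in CT26-like cells was -1.26 with an adjusted p of 0.0900, and with the low-RNA clusters added it was -1.28 with an adjusted p of 0.0816 (edgeR with Benjamini-Hochberg).

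**Figure D1:**
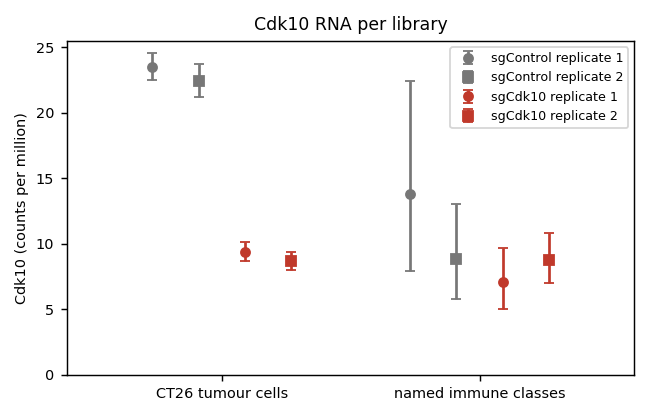
Cdk10 level in counts per 1e6 UMIs (CPM), 1 point per library, in CT26-like cells and in all named immune-like classes together, with 95% counting intervals as bars. In CT26-like cells both sgCdk10 libraries (9.38 and 8.66 CPM) sit below both sgControl libraries (23.5 and 22.4 CPM), and in immune-like classes the intervals of the libraries overlap.

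The next comparison asked which cells made up the tumours. CD8 T-like cells, the class of cytotoxic T cells, were 0.0125% and 0.0639% of cells in sgControl (2 and 16 cells) and 0.905% and 2.41% in sgCdk10 (212 and 408 cells), or 0.0382% ± 0.0363 against 1.66% ± 1.06 (SD, n = 2). They rose by 5.38 ± 1.49 (adjusted p = 0.0185, edgeR on cell numbers with Benjamini-Hochberg). All immune cells together, unnamed immune clusters included, were 2.77% and 6.89% in sgControl and 12.7% and 21.5% in sgCdk10 (4.83% ± 2.91 against 17.1% ± 6.28, SD, n = 2). NK-like cells were 0.15%, 0.775%, 1.66% and 4.56% (log2 fold change 2.74 ± 1.31, adjusted p = 0.229) and macrophage/monocyte-like cells 1.74%, 2.62%, 7.26% and 8.95% (1.89 ± 1.24, adjusted p = 0.329). In both, each sgCdk10 library lay above each sgControl library, but the difference did not pass the test (edgeR with Benjamini-Hochberg).

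CD4 T-like cells were 0.156%, 1.35%, 1.17% and 1.73% of cells (log2 fold change 0.94 ± 1.24, adjusted p = 0.589, edgeR with Benjamini-Hochberg here and below). Regulatory T-like cells were 0.0875%, 0.479%, 0.350% and 1.06% (1.30 ± 1.26, adjusted p = 0.538). Dendritic-like cells were 0.119%, 0.511%, 0.538% and 0.886% (1.17 ± 1.24, adjusted p = 0.538). Neutrophil-like cells were 0.45%, 0.559%, 0.294% and 0.543% (-0.27 ± 1.21, adjusted p = 0.930), and CT26-like cells 59.1%, 31.4%, 44.9% and 46.4% (0.01 ± 1.2, adjusted p = 0.992). With TMM scaling of the cell numbers both were called as falls, neutrophil-like cells at -2.23 and CT26-like cells at -2.13 (adjusted p = 0.0423 each). B-like cells were 0%, 0.124%, 0.166% and 0.366% (2.05 ± 1.35, adjusted p = 0.329). The 0 of 16000 cells in sgControl_1 allows a share of up to 0.0188%. Median UMIs per barcode ranged from 2742.5 to 6816 and the low-RNA clusters from 21.9% to 45.2% of cells. Whether depth moves the share of CT26-like cells was not tested, and among cells with at least 1000 UMIs its change was 0.05. The CT26-like share leaves out the matrix-high clusters, whose Cdk10 and Def8 levels are near those of CT26-like cells. It also leaves out the low-RNA clusters, in which tumour cells are not ruled out.

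The call for CD8 T-like cells was lost without sgCdk10_1 (log2 fold change 5.93, adjusted p = 0.202), without sgCdk10_2 (4.52, adjusted p = 0.503), with classes by marker score (1.85, adjusted p = 0.308) and over named cells alone (4.76, adjusted p = 0.252), all in edgeR with Benjamini-Hochberg. Without sgControl_2 the test also called NK-like (4.37, adjusted p = 0.0115), CD4 T-like (3.21, adjusted p = 0.0326), regulatory T-like (2.99, adjusted p = 0.0377) and B-like cells (8.64, adjusted p = 0.0103). As a share of immune-like cells, CD8 T-like cells rose by 3.58 (adjusted p = 0.00488), neutrophil-like cells fell by 2.30 (adjusted p = 0.0263), and macrophage/monocyte-like cells were at -0.03 (edgeR with Benjamini-Hochberg).

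**Figure D2:**
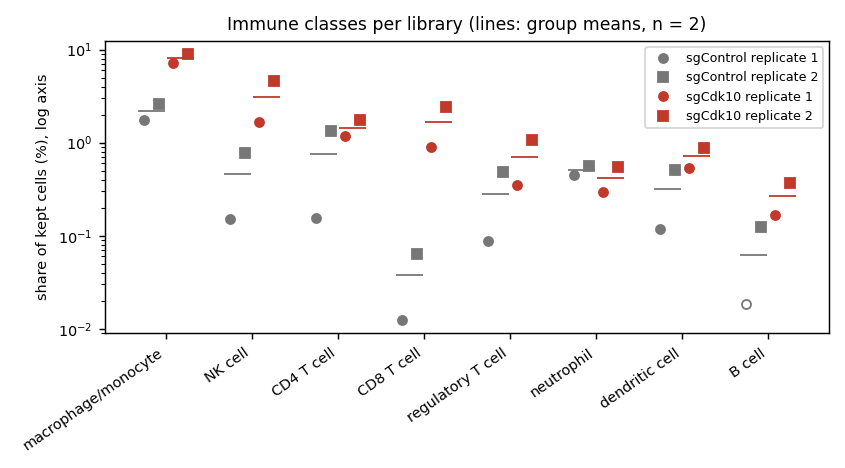
Share of each immune-like class among all kept singlet cells, in percent on a log axis, 1 point per library, with lines at the group means (n = 2) and an open marker for B-like cells of sgControl_1 at the upper limit (0.0188%) that 0 cells allow. CD8 T-like cells are at 0.0125% and 0.0639% in sgControl and at 0.905% and 2.41% in sgCdk10.

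Genes of CD8 T-like cells were not tested, because sgControl held 2 and 16 of them. In sgCdk10 the class carried the RNA of cytotoxic effectors: Gzmb (granzyme B) was at 3587 and 5597 CPM, Prf1 (perforin) at 2906 and 2950 CPM and Ifng (interferon-gamma) at 473 and 778 CPM. The inhibitory receptor genes Pdcd1 and Havcr2 were at 597 and 530.5 CPM and at 600 and 635 CPM, and Tcf7, a factor of naive and memory T cells, at 19.7 and 10.8 CPM. In sgControl_2, Gzmb had 11 UMIs (390 CPM), Prf1 12 (425 CPM), Ifng 2 (70.9 CPM), Pdcd1 26 (921 CPM), Tcf7 7 (248 CPM) and Havcr2 0. In sgControl_1 Pdcd1 had 12 UMIs and the other 5 genes 0, where 3 counts would be 523 CPM. Foxp3, the defining factor of regulatory T cells, was at 1009, 750, 737 and 895 CPM in the regulatory T-like class.

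In CT26-like cells 683 of 15792 genes changed, 412 up and 271 down (edgeR with Benjamini-Hochberg). The largest clusters of this class were 2 and 5 in sgControl and 7 and 8 in sgCdk10. Clusters 2 and 7 share histone genes and 5 and 8 are both high in Krt20, so this does not show a change of cell states. The interferon-led cluster 11 held 2.97% and 3.37% of the class in sgControl and 8.68% and 17.3% in sgCdk10. Areg-high cluster 10 went from 10.3% and 15.5% to 6.27% and 2.65%. Neither shift was tested. Without cluster 11 edgeR called 729 genes, 633 of them among the 683. The named rises were led by interferon-induced genes: the GTPase genes Iigp1 (3.97 ± 0.45, adjusted p = 0.0299; 15 and 13.4 CPM in sgControl, 128 and 318 in sgCdk10), Gbp10 (3.94 ± 0.49), Gbp6 (3.54 ± 0.44), Gbp2b (3.37 ± 0.51), Gbp2 (3.31 ± 0.49), Gbp3 (3.10 ± 0.42), Gbp7 (2.99 ± 0.37), Gbp5 (2.80 ± 0.38) and Irgm2 (2.77 ± 0.38). With them rose C1s1, a complement protease (3.02 ± 0.52), Ly6a (2.93 ± 0.29) and the nucleic acid sensor Zbp1 (2.90 ± 0.37). Guanylate-binding proteins are near-identical in places, so how the authors' counting split reads among the Gbp genes is uncertain. Cd274, which encodes PD-L1, rose by 2.41 ± 0.44 (adjusted p = 0.0488, edgeR with Benjamini-Hochberg).

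Interferon lists rose as groups in these cells. Of 40 measured members of the type I interferon response, 28 rose over all genes and 36 adjusted over the list alone, none fell, and the median was 1.13 (camera adjusted p = 1.33e-43), with Rtp4 at 2.03 ± 0.23 and Parp14 at 1.65 ± 0.21. Of 17 interferon-gamma response members 12 rose, 16 adjusted over the list alone (median 2.80, camera adjusted p = 3.87e-32), with Serpina3g at 5.17 ± 0.40 and Ido1, an enzyme of tryptophan breakdown, at 3.94 ± 0.33. Of 18 MHC class I presentation members 12 rose, 16 adjusted over the list alone (median 1.06, camera adjusted p = 2.00e-23), with Psmb9 at 2.60 ± 0.26, the peptide transporter Tap1 at 2.07 ± 0.23 and Psmb8 at 1.85 ± 0.15. The class I heavy chain gene H2-K1 rose by 0.88 ± 0.13 (adjusted p = 0.0392, edgeR with Benjamini-Hochberg). Each of these lists had an adjusted p = 0.33 with an estimated correlation.

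Class II and sensor genes were also higher. Of 9 MHC class II presentation members 6 rose, 8 adjusted over the list alone (median 3.67, camera adjusted p = 5.87e-19, adjusted p = 0.33 with an estimated correlation), with H2-Eb1 at 4.41 ± 0.79 and H2-DMb2 at 4.38 ± 0.43. H2-DMb1 had 3 UMIs in sgControl and 147 in sgCdk10, a ratio of 49.9 (95% counting interval 16.7 to 245). Genes of leukocytes in the same cells were at 0.331, 2.22, 3.10 and 3.64 CPM for Ptprc (log2 fold change 1.48, adjusted p = 0.275), and C1qa, a macrophage gene, rose from 0.740 and 1.24 to 3.47 and 3.83 CPM (1.92, adjusted p = 0.0400, edgeR with Benjamini-Hochberg). Of 27 nucleic acid sensing members 10 rose, and adjusted over the list alone 13 rose and 1 fell (median 0.44, camera adjusted p = 3.67e-08, adjusted p = 0.33 with an estimated correlation).

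Among single sensors in CT26-like cells, Ifih1, which encodes the RNA sensor MDA5, rose by 1.37 ± 0.09 (adjusted p = 0.0211), Ddx58, which encodes RIG-I, by 0.95 ± 0.10 (adjusted p = 0.0260) and Tmem173, which encodes STING, by 0.86 ± 0.10 (adjusted p = 0.0332, edgeR with Benjamini-Hochberg). Samhd1, which encodes an enzyme that limits DNA synthesis from viral RNA, rose by 1.39 ± 0.21. Cgas, the sensor of cytosolic DNA, was at -0.24 ± 0.11 (adjusted p = 0.227). Ifnb1, the gene of interferon-beta, had 2, 3, 9 and 1 UMIs and was not tested. Isg15 rose by 1.62 ± 0.29 (adjusted p = 0.0475), and Ccl5 was at 0.87 ± 0.25 (adjusted p = 0.0984, edgeR with Benjamini-Hochberg). Of 14 chemokines 2 rose, 8 adjusted over the list alone (median 1.24, camera adjusted p = 7.24e-05, adjusted p = 0.489 with an estimated correlation), Ccl8 by 3.40 ± 0.60 (from 6, 5, 30 and 89 UMIs) and Ccl4 by 2.96 ± 0.53 (from 2, 2, 13 and 19 UMIs). Ccl8 is a leading gene of a macrophage subcluster, at 152 and 331 CPM in macrophage/monocyte-like against 0.466 and 1.12 CPM in CT26-like cells of sgCdk10, and C1qa rose in CT26-like cells too. RNA of leukocytes was not tested as the source of the chemokines.

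Other groups of CT26-like cells moved as well. Of 24 hypoxia and glycolysis members 9 rose, 19 adjusted over the list alone (median 0.54, camera adjusted p = 4.10e-16, adjusted p = 0.33 with an estimated correlation), with Ankrd37 at 1.24 ± 0.12, the mitophagy gene Bnip3 at 1.24 ± 0.14 and Pdk1, which limits pyruvate use in mitochondria, at 1.16 ± 0.14. Of 22 members of the dissociation stress and immediate early list 3 rose, 9 adjusted over the list alone (median 0.75, camera adjusted p = 1.24e-08, adjusted p = 0.560 with an estimated correlation): Zfp36 (1.2 ± 0.11), Junb (1.10 ± 0.14) and Jund (0.80 ± 0.10). Of 21 NF-kB response members 1 rose, Bcl2a1b (3.37 ± 0.62), also adjusted over the list alone (median 0.43, camera adjusted p = 0.000194, adjusted p = 0.656 with an estimated correlation). Whether leukocyte RNA adds to Bcl2a1b was not tested. Of 48 G2/M phase members 0 passed the edgeR test over all genes or adjusted over the list alone, while 4360 genes of the class had an unadjusted p under 0.05 and DESeq2 called 2016. The G2/M list lay lower as a whole (median -0.08, camera adjusted p = 0.0159, adjusted p = 0.737 with an estimated correlation), a call lost without sgControl_1 (camera adjusted p = 0.27), with matrix-high (0.787) or low-RNA clusters added (0.126) and with classes by marker score (0.169). Without the interferon-led cluster the list changed direction (0.902). Kif20b was at -0.38 (adjusted p = 0.0515, edgeR with Benjamini-Hochberg).

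The remaining lists of CT26-like cells did not pass camera. In the matrix and mesenchymal list of 29, 3 rose and 5 fell, or 5 and 6 adjusted over the list alone (median 0.09, adjusted p = 0.499): Thbs2, a matrix glycoprotein, rose by 2.00 ± 0.08 (adjusted p = 0.00598, edgeR with Benjamini-Hochberg), and Ccn2 and the collagen gene Col3a1 fell by 1.05 ± 0.18 and 0.84 ± 0.07. In the S phase list of 36, Mcm4 rose by 0.51 ± 0.07, over all genes and adjusted over the list alone (median 0.04, adjusted p = 0.645). In the p53 target list of 21, Polk fell by 0.56 ± 0.07, and adjusted over the list alone 2 rose and 4 fell (median 0.00, mean 0.13, test downward, adjusted p = 0.869). In the DNA methylation and silencing list of 24, Tasor fell by 0.53 ± 0.07, and adjusted over the list alone 3 fell (median -0.12, adjusted p = 0.0915). Oxidative phosphorylation (48 members, median 0.06, adjusted p = 0.498, Uqcrq at 0.46) and MAPK and ETS output (22, median 0.19, adjusted p = 0.102, Spry2 at 0.57) held no member that edgeR called over all genes. The same was so for the unfolded protein response (21, median 0.04, mean 0.02, test downward, adjusted p = 0.925, Xbp1 at -0.40). Counts of 0 in these 3 lists stand beside the 4360 genes of the class with an unadjusted p under 0.05 and the 2016 called by DESeq2. Camera called oxidative phosphorylation without sgControl_1 (adjusted p = 0.00494), MAPK and ETS output without sgControl_2 (0.00287), and DNA methylation and silencing without sgControl_2 (0.0466) or sgCdk10_2 (0.0202).

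**Figure D3:**
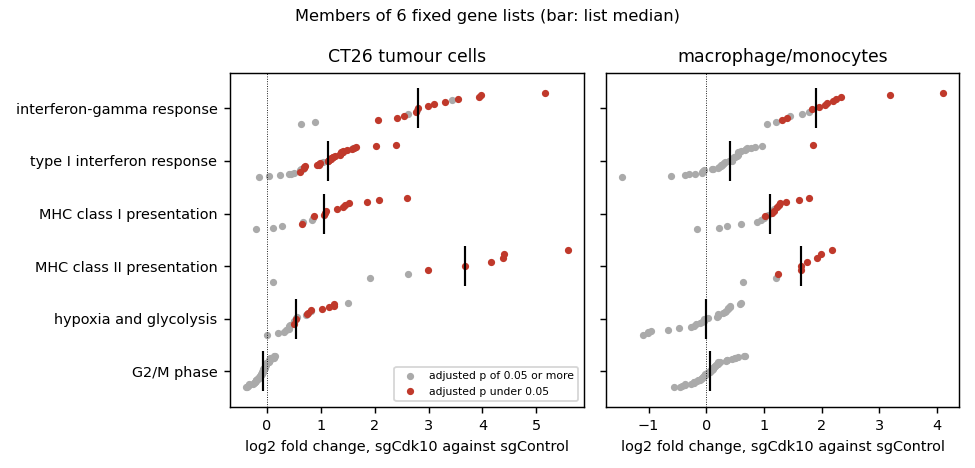
Log2 fold change (sgCdk10 over sgControl) of each measured member of 6 gene lists in CT26-like (left) and macrophage/monocyte-like cells (right), 1 point per gene, red where the edgeR adjusted p over all genes is under 0.05, with a bar at the list median. In CT26-like cells the medians of the interferon-gamma response (2.80) and MHC class II presentation (3.67) lie furthest from 0.

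The named falls in CT26-like cells were led by Krt18, an epithelial keratin, from 48.5 and 62.0 to 14.2 and 9.98 CPM (-2.19 ± 0.21, adjusted p = 0.0254, edgeR with Benjamini-Hochberg). Next were Dhrs9, a retinol dehydrogenase (-1.41 ± 0.15), Ppef1 (-1.30 ± 0.21), Tenm4 (-1.24 ± 0.22), Acsbg1 (-1.16 ± 0.19), Ankle1 (-1.09 ± 0.19) and the myosin gene Myh14 (-1.09 ± 0.10). Phyhd1 (-1.05 ± 0.10), Fkbp5, a glucocorticoid-induced co-chaperone (-0.97 ± 0.18, adjusted p = 0.0488), Garem1 (-0.94 ± 0.10), Tenm3 (-0.92 ± 0.08) and Fam120c (-0.92 ± 0.10) completed them. Krt18 was 1 of the markers of the class. The count of changed genes was 245 without sgControl_1, 2045 without sgControl_2, 96 without sgCdk10_1 and 41 without sgCdk10_2, of which 205, 660, 92 and 41 were among the 683. Rises and falls numbered 174 and 71, 1356 and 689, 91 and 5, and 39 and 2 in the same order. Of 57 named genes called besides Cdk10, 33, 57, 29 and 20 kept their call in the same order, and 11 kept it whichever library was left out: Dhrs9, Gbp7, Ifih1, Iigp1, Ly6a, Psmb9, Rtp4, Serpina3g, Tap1, Thbs2 and Zbp1. The count was 60 with the matrix-high clusters added, 49 with classes by marker score and 4 (Tex14, Thbs2, Cfb and AC133103.1, of which Tex14, Cfb and AC133103.1 were chosen after their values were seen) with the low-RNA clusters added. Cdk10 was lower in sgCdk10 in the matrix-high (22.9, 23.6, 11 and 9.96 CPM) and the low-RNA clusters (23.7, 18.2, 9.33 and 7.94 CPM) too. How many genes changed in the tumour cells therefore depends on whether these clusters are counted among them, and 683 covers the named clusters alone.

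In macrophage/monocyte-like cells 149 of 10281 genes changed, 88 up and 61 down (edgeR with Benjamini-Hochberg). Rises were led by Ly6a (4.76 ± 0.41, adjusted p = 0.00632), Serpina3f (4.38 ± 0.56), Serpina3g (4.11 ± 0.47), the PD-L2 gene Pdcd1lg2 (3.25 ± 0.32), Cxcl9, a chemokine that attracts T cells (3.19 ± 0.48, adjusted p = 0.0208), and Acod1, which makes itaconate (3.11 ± 0.39, adjusted p = 0.0129). Timd4 (3.06 ± 0.56), Calhm6 (3.03 ± 0.48) and Il12rb1 (2.98 ± 0.49) rose too, and Tnik went from 3 to 228 UMIs, a ratio of 21.9 (95% counting interval 7.41 to 107). Timd4 is also a leading gene of a dendritic-like subcluster, and Calhm6 of the unnamed one with NK, CD8 T and macrophage genes together. Whether RNA of other leukocytes adds to these rises was not tested. Falls were led by Fcrls (-3.91 ± 0.56, adjusted p = 0.0168), Ednrb (-2.64 ± 0.24), Fkbp5 (-2.38 ± 0.43, adjusted p = 0.0377), Rgs18 (-2.29 ± 0.32) and Lyve1, a hyaluronan receptor of resident macrophages (-2.18 ± 0.18, adjusted p = 0.00632). Then came Lsamp (-2.06 ± 0.35), fibronectin gene Fn1 (-2.01 ± 0.25), Stxbp6 (-1.90 ± 0.25), F13a1 (-1.89 ± 0.22) and the haemoglobin scavenger receptor gene Cd163 (-1.88 ± 0.17, adjusted p = 0.00632, edgeR with Benjamini-Hochberg).

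Cd274 also rose in macrophage/monocyte-like cells (1.96 ± 0.24, adjusted p = 0.0129), and Spp1, the osteopontin gene, fell from 1442 and 1348 to 675 and 527 CPM (-1.21 ± 0.18, adjusted p = 0.0202, edgeR with Benjamini-Hochberg). Free tumour RNA can add to Spp1: CT26-like cells held it at 6795 to 8576 CPM. Other classes held it at 2721, 2230, 3630 and 3730 CPM (NK-like), 1095, 1265, 1969 and 2689 CPM (neutrophil-like) and 44.5, 494, 551 and 258 CPM (CD4 T-like), which can include RNA of their own. In macrophages the tumour genes Tm4sf1, Hmga2 and Krt20 lay at 1.09% to 6.17% of their level in CT26-like cells. At the same shares free Spp1 would lie below the macrophage level in each library, and in sgControl this also holds for Areg and Krt8. In sgCdk10 the shares of Areg (11.4% in sgCdk10_2) and Krt8 (13.3% and 10.6%), which had low levels in CT26-like cells, would put it above, so how much of the sgCdk10 level is free RNA stays open. Arg1 (-0.50 ± 0.28, adjusted p = 0.479), Nos2 (1.65 ± 0.75, adjusted p = 0.381) and C1qa (0.58 ± 0.22, adjusted p = 0.281) did not pass the same test. The count of changed genes was 6 without sgControl_1 (0 up, 6 down), 69 without sgControl_2 and 499 without sgCdk10_1, of which 5, 41 and 145 were among the 149, and 3 with classes by marker score (Clec12a, Mmp13 and Ighm, chosen after their values were seen). Of 33 named genes called, 5 kept their call without sgControl_1, 13 without sgControl_2 and 33 without either sgCdk10 library, and Cd163, Ednrb, F13a1 and Lyve1 kept it whichever library was left out.

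By list, interferon-gamma response and antigen presentation genes rose in macrophage/monocyte-like cells. Of 16 interferon-gamma response members 11 rose, 15 adjusted over the list alone (median 1.90, camera adjusted p = 8.26e-42), with Gbp2 at 2.33 ± 0.28. Of 18 class I members 9 rose, 15 adjusted over the list alone (median 1.11, camera adjusted p = 1.22e-24), with Tap1 at 1.78 ± 0.20, Psmb9 at 1.61 ± 0.21 and Psmb8 at 1.39 ± 0.23. Of 9 class II members 7 rose, 9 adjusted over the list alone (median 1.64, camera adjusted p = 2.51e-19), with H2-Eb1 at 2.18 ± 0.36, H2-Ab1 at 1.99 ± 0.34 and H2-Aa at 1.92 ± 0.32. Of 12 inflammatory macrophage members 3 rose, 6 adjusted over the list alone (median 1.23, camera adjusted p = 1.14e-11), among them Cd40 (1.63 ± 0.31). The suppressive and repair list of 24 lay lower (median -0.23, camera adjusted p = 0.000908), with 1 member up, the lipid receptor gene Cd36 (1.5 ± 0.20), and 4 down, or 1 up and 6 down adjusted over the list alone. All 5 lists had an adjusted p = 0.33 with an estimated correlation, and the suppressive list lost its call without sgCdk10_1 (camera adjusted p = 0.0762). With classes by marker score, which let CT26-like cells into immune-like classes, the suppressive list was called upward instead (camera adjusted p = 0.000739).

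Smaller shifts were found in other lists of this class. Of 40 type I interferon members 1 rose, and adjusted over the list alone 3 rose and 1 fell (median 0.42, camera adjusted p = 6.18e-06, adjusted p = 0.634 with an estimated correlation). Of 28 nucleic acid sensing members 1 rose, Samhd1 (1.01 ± 0.19), and 3 adjusted over the list alone (median 0.14, camera adjusted p = 0.00754, adjusted p = 0.489 with an estimated correlation). Both calls were lost without sgCdk10_2 (camera adjusted p = 0.0616 for each). S phase (33 members, median 0.53, camera adjusted p = 3.67e-08, adjusted p = 0.489 with an estimated correlation, Mcm4 at 0.68) held 0 members called by edgeR, over all genes or adjusted over the list alone, and lost its call with classes by marker score (camera adjusted p = 0.245). NF-kB response (22 members, median 0.38, camera adjusted p = 1.71e-06, adjusted p = 0.560 with an estimated correlation, Sod2 at 1.06) held 0 over all genes and 6 up adjusted over the list alone, and lost its call without sgControl_1 (camera adjusted p = 0.0947). Chemokines (14 members, 1 up, 3 up and 3 down adjusted over the list alone, median 0.09, adjusted p = 0.318), G2/M phase (48, median 0.06, adjusted p = 0.555, Rangap1 at 0.67), hypoxia and glycolysis (26, median -0.01, adjusted p = 0.930, Pfkp at 0.60) and dissociation stress (22, median 0.13, adjusted p = 0.318, Junb at 0.59) did not pass camera. With 1 library left out camera called G2/M phase (upward without sgControl_2, adjusted p = 0.0306, or sgCdk10_2, 7.44e-05, and downward without sgCdk10_1, 0.0427), hypoxia (downward without sgControl_2, 0.00378, and upward without sgControl_1, 0.00494) and dissociation stress (upward without sgControl_2, 0.000255, or sgCdk10_2, 0.0323). Over the class 1403 genes had an unadjusted p under 0.05, and DESeq2 called 212.

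Some unnamed immune subclusters were kept out of every named class and its share. They include cells with NK, CD8 T and macrophage genes together (0, 5, 39 and 95 cells) and cells with granzyme genes and few UMIs (0, 7, 17 and 38 cells). In NK-like cells (24, 194, 388 and 772 cells), which leave these out, 2 of 7218 genes changed. Gzmb rose from 3267 and 4433 to 7971 and 7487 CPM (0.98 ± 0.14, adjusted p = 0.0108), and Dscam fell by 2.00 ± 0.18 (adjusted p = 8.36e-05, edgeR with Benjamini-Hochberg). Both kept their call whichever library was left out. Of 22 cytotoxic effector members 1 rose, and adjusted over the list alone 7 rose and 1 fell (median 0.31, camera adjusted p = 6.71e-08, adjusted p = 0.33 with an estimated correlation). Gzmf, a member at 0 in both sgControl libraries, was at least 3.69-fold higher against 3 counts over the group, and the median with it at that bound was 0.31. MHC class I members (18, median 0.13, camera adjusted p = 0.00573, adjusted p = 0.33 with an estimated correlation, Psmb9 at 0.86) lost the call without sgCdk10_1 (0.0510) and changed direction with equal cell numbers (0.378). Interferon-gamma response members (13, 2 up adjusted over the list alone, median 0.20, camera adjusted p = 0.0240, adjusted p = 0.629 with an estimated correlation, Irf1 at 0.77) lost it without sgControl_2 (0.0973), without sgCdk10_2 (0.259) and with equal cell numbers (0.281).

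In the same NK-like cells G2/M phase members (45, median 0.21, camera adjusted p = 0.00121, adjusted p = 0.663 with an estimated correlation, Ckap2l at 1.16) lost the call without sgControl_2 (0.0973) and without sgCdk10_1 (0.433), and were called downward with classes by marker score (0.0204). Dissociation stress members (21, 1 up adjusted over the list alone, median 0.37, camera adjusted p = 1.23e-07, adjusted p = 0.433 with an estimated correlation) included Junb at 0.88 (edgeR adjusted p = 0.106 with Benjamini-Hochberg). Type I interferon (31, median 0.09, adjusted p = 0.569) and S phase members (34, median -0.15, adjusted p = 0.519, Cdca7 at -1.32) did not pass camera. Without sgControl_2 camera called type I interferon (adjusted p = 0.0306), and it called S phase in opposite directions without sgControl_1 (0.00359) and without sgControl_2 (0.0188). Apart from Gzmb, edgeR called 0 members of the tested lists over all genes in NK-like cells, where 451 genes had an unadjusted p under 0.05 and DESeq2 called 2. The count of changed genes was 47 without sgControl_1, 80 without sgControl_2, 7 without sgCdk10_1 and 4 without sgCdk10_2 (Gzmb, Dscam and, chosen after their values were seen, Hbb-bs and Gvin1).

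In CD4 T-like cells (25, 337, 273 and 293 cells) 3 of 6023 genes changed. Ccl5, a chemokine of activated T cells, rose by 1.88 ± 0.28 (adjusted p = 0.0188), and Top2a, a topoisomerase of dividing cells, fell by 1.6 ± 0.27 (adjusted p = 0.0484, edgeR with Benjamini-Hochberg). The other was the haemoglobin gene Hbb-bs, outside the naming rule and chosen after its values were seen, with 0, 316, 11 and 3 UMIs. RNA of NK-like and CD8 T-like cells, whose shares were higher in both sgCdk10 libraries, was not tested as a source of the Ccl5 rise. G2/M phase members lay lower (31 members, 1 down, 11 down adjusted over the list alone, median -0.71, camera adjusted p = 2.07e-21, adjusted p = 0.33 with an estimated correlation). With classes by marker score, which kept 39.1% of these cells and let CT26-like cells into immune-like classes, the list was called upward (camera adjusted p = 0.011). Top2a was then at 0.39. Without sgCdk10_1 edgeR called 0 genes (138 with an unadjusted p under 0.05), and it called 81 without sgControl_1, 77 without sgControl_2 and 5 without sgCdk10_2 (Ccl5, Hbb-bs and, chosen after their values were seen, Gzma, Gzmc and Gm42047, but not Top2a). DESeq2 called 0 (52 with an unadjusted p under 0.05).

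Interferon-gamma response members of CD4 T-like cells (13, median 0.44, camera adjusted p = 0.00587, adjusted p = 0.489 with an estimated correlation, Gbp2 at 0.63) lost the call without sgControl_1 (0.0947), without sgCdk10_2 (0.147) and with equal cell numbers (0.077). MHC class I members (18, median 0.17, camera adjusted p = 0.0173, adjusted p = 0.480 with an estimated correlation, H2-T22 at 0.44) lost it without sgControl_1 (0.104), without sgCdk10_2 (0.363) and with equal cell numbers (0.378). Dissociation stress members lay lower (20, 2 down adjusted over the list alone, median -0.17, camera adjusted p = 0.0109, adjusted p = 0.560 with an estimated correlation, Hsph1 at -1.42), a call lost without sgControl_2 (0.893) and with doublets kept (0.204). They changed direction with equal cell numbers (0.832) and were called upward with classes by marker score (0.0286). Type I interferon (37, median -0.29, adjusted p = 0.215, Oasl1 at -1.65), naive and memory T cell (11, median -0.18, adjusted p = 0.0739, Il7r at -0.76) and S phase members (28, median -0.04, adjusted p = 0.498, Rrm2 at -0.94) did not pass camera. Camera called type I interferon downward without sgControl_1 (adjusted p = 5.48e-07) and upward without sgControl_2 (0.000398), and naive and memory genes without sgControl_2 (0.0141) or sgCdk10_2 (0.00924). In these 6 lists edgeR called 0 members over all genes, beside 352 genes of the class with an unadjusted p under 0.05 and 0 called by DESeq2.

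In neutrophil-like cells 14 of 1488 genes changed, all upward (edgeR with Benjamini-Hochberg). The interferon-induced genes Ifit2 (5.15 ± 0.70, adjusted p = 0.00691, from 3, 1, 26 and 98 UMIs), Ifit3 (4.39 ± 0.68, adjusted p = 0.0124) and Oasl2 (3.96 ± 0.63, adjusted p = 0.0124) led them. Of 23 type I interferon members 8 rose, 21 adjusted over the list alone (median 2.12, camera adjusted p = 1.21e-40). Of 7 interferon-gamma response members 3 rose, 7 adjusted over the list alone (median 2.64, camera adjusted p = 7.63e-14): Gbp5 (3.43 ± 0.69), Irgm1 (2.89 ± 0.58) and Gbp2 (2.43 ± 0.52). Of 7 class I members 1 rose, Psme2 (3.12 ± 0.68), and 6 adjusted over the list alone (median 1.45, camera adjusted p = 1.51e-07). These 3 lists had an adjusted p = 0.33 with an estimated correlation, and kept their camera call whichever library was left out. Free tumour RNA reached this class: the tumour gene Hmga2 lay at 148, 268, 122 and 175 CPM in it, against 1387, 1242, 940 and 987 CPM in CT26-like cells. In sgCdk10 the levels in neutrophil-like cells were above those in CT26-like cells for Ifit2 (672 and 1516 against 39.7 and 48.6 CPM), Ifit3 (491 and 1655 against 52.9 and 75.9), Oasl2 (336 and 805 against 151 and 204) and Gbp5 (336 and 1532 against 62.6 and 141). Psme2 lay below (233 and 294 against 472 and 587 CPM), so free tumour RNA can add to its rise.

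Chemokines (4 members, median 0.17, mean -0.04, test downward, adjusted p = 0.872, Cxcl3 at -1.08), G2/M phase (4, median -0.12, adjusted p = 0.717, Tubb4b at -0.60), hypoxia and glycolysis (19, median -0.18, adjusted p = 0.498, Ero1l at -0.68), NF-kB response (10, median 0.02, adjusted p = 0.747, Tnfaip2 at 0.90) and dissociation stress members (17, median 0.08, adjusted p = 0.790, Atf3 at 0.63) of neutrophil-like cells did not pass camera. Hypoxia was called in opposite directions without sgControl_2 (adjusted p = 0.000322) and without sgControl_1 (0.0132). The count of changed genes was 24 without sgControl_1, 43 without sgCdk10_1 and 3 without sgCdk10_2 (Ifit2 and, chosen after their values were seen, Rsad2 and Hbb-bs). It was 0 in edgeR without sgControl_2, with 154 genes at an unadjusted p under 0.05, and DESeq2 with all libraries called 14. Of 7 named genes called, 5 kept their call without sgControl_1, 0 without sgControl_2, 6 without sgCdk10_1 and 1 without sgCdk10_2. Over the 5 classes camera called 31 of the 52 list tests, 10 of 17 in CT26-like and 9 of 13 in macrophage/monocyte-like cells, and none of the 31 with an estimated correlation or by the directional fry test (lowest adjusted p = 0.255). In fry's mixed test, which takes changes either way, 6 of the 52 passed, 3 of them among the 31: G2/M phase and dissociation stress in CD4 T-like cells (adjusted p = 0.0371 each) and the suppressive list in macrophage/monocyte-like cells (adjusted p = 0.0386). The other 3, which camera did not call, were matrix and mesenchymal (adjusted p = 0.0371) and DNA methylation and silencing (adjusted p = 0.0386) in CT26-like cells and S phase in CD4 T-like cells (adjusted p = 0.0371).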

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

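No test in this part was chosen after its result was seen. The effect of sgCdk10 in CT26-like cells differed from that in macrophage/monocyte-like cells of the same tumours for 620 of 15708 genes, 368 higher and 252 lower in CT26-like cells (edgeR interaction with Benjamini-Hochberg). The lowest p belonged to the complement gene C4b, at 4.10 in CT26-like against 1.13 in macrophage/monocyte-like cells (from 1.32 and 1.33 to 17 and 28.5 CPM in CT26-like cells). Zbp1, at 2.90 against 0.99, was among the 8 lowest. The actin-binding gene Cnn3 went the other way, at 0.21 in CT26-like and 2.95 in macrophage/monocyte-like cells. The count was 1050 without sgControl_2, 377 without sgCdk10_1 and 217 without sgCdk10_2. With RLE scaling it was 660, with 498 higher and 162 lower.

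By list, the type I interferon response moved further in CT26-like cells (medians 1.13 and 0.42, camera adjusted p = 6.67e-17, adjusted p = 0.105 with an estimated correlation). So did the interferon-gamma response (2.80 and 1.90, adjusted p = 0.00123), MHC class II presentation (3.67 and 1.64, adjusted p = 3.82e-05, with RNA of leukocytes not excluded as the source), chemokines (1.24 and 0.09, adjusted p = 4.13e-05, with RNA of leukocytes not tested as the source), and dissociation stress and immediate early genes (0.75 and 0.13, adjusted p = 2.08e-07). Nucleic acid sensing genes did too (0.44 and 0.14, median difference 0.02, adjusted p = 0.0191). These last 5 lists had an adjusted p = 0.237 with an estimated correlation. Hypoxia and glycolysis was higher in CT26-like cells (0.54 and -0.01, adjusted p = 3.59e-05) and S phase lower (0.04 and 0.53, adjusted p = 7.35e-06), both with an adjusted p = 0.476 with an estimated correlation. MHC class I (adjusted p = 0.783), G2/M phase (0.0826) and NF-kB response (0.657) did not differ by this test, which does not show that they moved alike.

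RNA of leukocytes, carried over or joined in doublets, might raise immune genes in the CT26-like class of sgCdk10 tumours. Interferon-gamma response genes would need 21.2% and 31.5% of macrophage RNA, or 28.9% and 40.2% of dendritic cell RNA, in the 2 sgCdk10 libraries, while pan-leukocyte genes account for 0.130% and 0.177%, or 0.153% and 0.153%. The larger ratio of the leukocyte share to the share needed was 0.00617 for macrophages and 0.00531 for dendritic cells. These shares are medians over genes, and by them neither can be the whole source of the list's rise. The lowest member needed only 0.306% and 0.251% of macrophage RNA, or 0.109% and 0.200% of dendritic cell RNA. Single pan-leukocyte genes reached 0.310% and 0.223%, or 0.256% and 0.246%. For such members leukocyte RNA is not excluded. Class II genes need only 0.288% and 0.233% of macrophage RNA or 0.0903% and 0.195% of dendritic cell RNA, with ratios of 0.760 and 1.70, so class II RNA from other cells and from the tumour cells cannot be told apart. An effect of the Cdk10 guide in the tumour cells and a response to the larger share of CD8 T-like cells around them both stay open for the interferon genes, since the design does not separate them.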

How the results depend on the processing

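The tests added after the data were seen were those with the matrix-high, low-RNA or interferon-led clusters moved, the crossed pairing, and shares over named cells or cells with at least 1000 UMIs. Of alternative values, 557 for lists, 1291 for named genes and 81 for shares kept direction and side of the threshold. For lists 85 lost the call, 28 gained one and 55 changed direction, for named genes 443, 28 and 12 did, and for shares 4, 7 and 15 did. With 1 library of a group left, that library is assumed to vary like the other group's. With 2 libraries per group these refits are weak evidence, and the cause of a change below was not tested unless given. Neutrophil-like cells with stricter cells were not run (16 cells in 1 library). Recovery at 2-fold was lowest in neutrophil-like cells (7.78%), where the spread between libraries was also highest (biological coefficient of variation 0.268 against 0.0965 to 0.147 in the other classes), and what limits it was not tested. The number of cells, not depth, limits CD8 T-like cells: sgControl holds 2 and 16 of them, too few for a gene test. Cdk10 expression kept direction in CT26-like cells throughout, with an adjusted p of 1.98e-18 in DESeq2 and 0.0449 with the matrix-high clusters.

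For counts of changed genes (683 CT26-like, 149 macrophage/monocyte-like, 2 NK-like, 3 CD4 T-like, 14 neutrophil-like), DESeq2 gave 2016 in CT26-like and 0 in CD4 T-like cells (52 at an unadjusted p under 0.05). RLE scaling gave 6 in CD4 T-like (1 up, 5 down) and 6 in neutrophil-like cells. No filter gave 2117, 636, 35, 25 and 36. Marker score gave 49, 3, 0, 0 and 0 (1426, 318 and 1982 at an unadjusted edgeR p under 0.05 in the last 3). Equal cell numbers, which test fewer genes, gave 86 in macrophage/monocyte-like, 1 (Dscam) in NK-like and 7 in CD4 T-like cells, and doublets kept gave 23 in neutrophil-like cells. CT26-like cells gave 60 with matrix-high and 4 with low-RNA clusters added.

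The replicate numbers gave no sign of pairing the samples, by the correlation between same-numbered libraries of their deviations from the group means. It was -0.0864 in CT26-like, -0.0845 in macrophage/monocyte-like, -0.0238 in NK-like, -0.0321 in CD4 T-like and -0.177 in neutrophil-like cells. With 2 libraries per group the other pairing gives the same value with the sign turned, so pairing is not excluded. With the replicate block edgeR called 0 genes in CT26-like (3457 at an unadjusted p under 0.05), 26 in NK-like, 0 in CD4 T-like (237) and 4 in neutrophil-like cells (Zbp1, Oasl2, Ifit2 and Ifit3). In the block fit Cdk10 expression was at -1.32 (adjusted p = 0.0929), the NK-like share at 2.99 was called, and macrophage chemokines had a camera adjusted p of 0.0118. The block changed no other call of a list or share. A crossed pairing called 14 genes in neutrophil-like cells, 11 of them among the 14.

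With a library left out, counts ran from 41 to 2045 in CT26-like, 6 to 499 in macrophage/monocyte-like, 4 to 80 in NK-like, 0 to 81 in CD4 T-like and 0 to 43 in neutrophil-like cells, and from 217 to 1050 for the interaction. Cdk10 expression ran from -1.39 to -1.26 in CT26-like and from -0.69 to 0.88 in macrophage/monocyte-like cells, Arg1 in macrophage/monocyte-like cells from -0.88 to 0.0199 and Ero1l in neutrophil-like cells from -1.29 to 0.29. Shares ran from 4.52 to 6.98 for CD8 T-like, 1.84 to 4.37 for NK-like, 1.09 to 8.64 for B-like, 0.48 to 2.58 for dendritic-like, 0.10 to 3.21 for CD4 T-like, 0.30 to 2.99 for regulatory T-like, -0.78 to 0.11 for neutrophil-like and -0.37 to 0.54 for CT26-like cells.

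List adjusted p (camera) with a library left out ran, in CT26-like cells, from 0.000952 to 0.27 for G2/M phase, 0.0202 to 0.288 for DNA methylation, 0.00287 to 0.488 for MAPK, 0.403 to 0.848 for S phase, 0.00494 to 0.892 for oxidative phosphorylation, 0.588 to 0.892 for p53 targets and 0.0947 to 0.544 for the unfolded protein response. In macrophage/monocyte-like cells they ran from 2.42e-10 to 0.0616 for type I interferon, 0.00618 to 0.0616 for nucleic acid sensing, 7.44e-05 to 0.374 for G2/M phase, 1.11e-14 to 0.0947 for NF-kB, 0.0871 to 0.754 for chemokines, 0.000255 to 0.648 for dissociation stress, 0.00378 to 0.883 for hypoxia and 0.000168 to 0.0762 for the suppressive list. In NK-like cells they ran from 0.0306 to 0.896 for type I interferon, 0.00316 to 0.259 for interferon-gamma, 0.00758 to 0.051 for class I, 0.00359 to 0.591 for S phase and 1.68e-08 to 0.433 for G2/M phase. In CD4 T-like cells they ran from 5.48e-07 to 0.654 for type I interferon, 0.00041 to 0.147 for interferon-gamma, 0.0105 to 0.363 for class I, 0.00924 to 0.659 for naive and memory genes and 6.43e-07 to 0.893 for dissociation stress. In neutrophil-like cells they ran from 0.433 to 0.848 for G2/M phase, 0.106 to 0.654 for NF-kB, 0.0947 to 0.907 for chemokines, 0.316 to 0.997 for dissociation stress and 0.000322 to 0.838 for hypoxia.

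With an estimated correlation no call was kept. In CT26-like cells the adjusted p was 0.489 for chemokines, 0.656 for NF-kB, 0.560 for dissociation stress, 0.737 for G2/M phase and 0.33 for the other 6. In macrophage/monocyte-like cells it was 0.634 for type I, 0.489 for sensing and S phase, 0.560 for NF-kB and 0.33 for the other 5. In NK-like cells it was 0.629 for interferon-gamma, 0.663 for G2/M phase, 0.433 for dissociation stress and 0.33 for class I and cytotoxic genes. In CD4 T-like cells it was 0.489 for interferon-gamma, 0.480 for class I, 0.560 for dissociation stress and 0.33 for G2/M phase, and in neutrophil-like cells 0.33 for all 3. By fry's directional test, which asks whether a list's genes move one way, the 10 CT26-like calls had an adjusted p of 0.255 (type I, class I, class II, sensing and hypoxia), 0.30 (interferon-gamma), 0.307 (chemokines), 0.328 (dissociation stress) and 0.401 (G2/M phase and NF-kB). In macrophage/monocyte-like cells it was 0.408 for type I, 0.307 for interferon-gamma, class II and sensing, 0.255 for class I and the suppressive list, 0.328 for S phase, 0.401 for NF-kB and 0.320 for the inflammatory list. In NK-like cells it was 0.425 for interferon-gamma, 0.255 for class I, 0.307 for cytotoxic genes, 0.564 for G2/M phase and 0.401 for dissociation stress. In CD4 T-like cells it was 0.408 for interferon-gamma, 0.399 for class I, 0.255 for G2/M phase and 0.545 for dissociation stress, and in neutrophil-like cells 0.307, 0.399 and 0.320 for type I, interferon-gamma and class I. Unfolded protein response and p53 lists of CT26-like cells and chemokines of neutrophil-like cells changed direction in fry (0.998 each).

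Marker score put every cell, low-RNA cells included, into 1 of the named classes, so CT26-like and unnamed cells entered the immune-like classes. Genes tested rose from 1488 to 12207 in neutrophil-like and from 7218 to 10940 in NK-like cells. Changes by this score therefore do not test the immune-like results cleanly. Classes by marker score changed the direction of these lists (camera adjusted p): the unfolded protein response in CT26-like cells (0.479), G2/M phase (0.516), hypoxia (7.28e-07) and the suppressive list (0.000739) in macrophage/monocyte-like cells, G2/M phase (0.0204) in NK-like cells, type I interferon (1.33e-05), S phase (0.718), G2/M phase (0.011) and dissociation stress (0.0286) in CD4 T-like cells, and chemokines (8.5e-07) and hypoxia (1.07e-10) in neutrophil-like cells. With direction kept, calls were lost for G2/M phase in CT26-like (0.169) and S phase in macrophage/monocyte-like cells (0.245). They were gained for MAPK (0.00882) in CT26-like, chemokines (9.42e-08) and dissociation stress (1.04e-05) in macrophage/monocyte-like, type I interferon (8.16e-23) in NK-like, and NF-kB (5.48e-08) and dissociation stress (3.18e-07) in neutrophil-like cells. By this score Top2a (0.39), Oasl1 (0.74) and Rrm2 (0.37) of CD4 T-like cells, Cdk10 (-0.79) and Arg1 (0.25) of macrophage/monocyte-like cells, and Tubb4b (0.17) and Ero1l (0.37) of neutrophil-like cells changed sign. Shares changed sign for CT26-like (-0.67) and B-like cells (-0.74), and the CD8 T-like share (1.85) lost its call. DESeq2 gave Cdk10 in macrophage/monocyte-like cells -0.0524.

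Equal cell numbers changed the direction of G2/M phase (0.425) and hypoxia (0.953) in macrophage/monocyte-like cells, class I (0.378) and S phase (0.811) in NK-like cells, and type I interferon (0.50) and dissociation stress (0.832) in CD4 T-like cells. They ended the calls of interferon-gamma in NK-like (0.281) and of interferon-gamma (0.077) and class I (0.378) in CD4 T-like cells, and gave calls for type I interferon in NK-like (0.0383) and naive and memory genes in CD4 T-like cells (0.000164). No filter gave calls for DNA methylation in CT26-like (0.0356) and naive and memory genes in CD4 T-like cells (0.0284), and changed the direction of chemokines (0.0473), G2/M phase (0.40) and dissociation stress (0.988) in neutrophil-like cells. Doublets kept ended the call of dissociation stress in CD4 T-like cells (0.204). In CT26-like cells the low-RNA clusters ended the call of G2/M phase (0.126), gave calls for MAPK (0.0375) and DNA methylation (0.0395) and changed the direction of the unfolded protein response (0.669), with Cdk10 expression at -1.28. Matrix-high clusters ended the call of G2/M phase (0.787) and changed the direction of the matrix list (0.279) and the unfolded protein response (0.712). Leaving out the interferon-led cluster changed the direction of G2/M phase (0.902) and of the unfolded protein response (0.872).

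Shares of immune-like cells in place of all cells were -0.0251 for macrophage/monocyte-like, -0.57 for CD4 T-like, -0.44 for regulatory T-like, -2.30 for neutrophil-like and -0.51 for dendritic-like cells, because the total then rises with the immune cells. TMM scaling of cell numbers gave -2.13 for CT26-like (adjusted p = 0.0423), -0.35 for CD4 T-like, -0.27 for regulatory T-like, -2.23 for neutrophil-like (adjusted p = 0.0423) and -0.34 for dendritic-like cells in edgeR with Benjamini-Hochberg. Named cells as the total gave -0.27 for CT26-like and 4.76 for CD8 T-like cells, and doublets kept gave -0.0123 for CT26-like cells.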

Other observations

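The tests chosen after the result was seen were that of Fkbp5 against other tumour genes and that of the chromosome medians as copy number. Among glucocorticoid-induced genes of macrophage/monocyte-like cells, Tsc22d3, which encodes the leucine zipper protein GILZ, fell by 1.64 (adjusted p = 0.0115) and the transcription factor gene Zbtb16 fell by 2.55 (adjusted p = 0.0361, edgeR with Benjamini-Hochberg). In CT26-like cells Tsc22d3 fell by 0.60 (adjusted p = 0.0371), while Sgk1, a kinase gene, and Lcn2, an iron-binding protein gene, rose by 1.19 (adjusted p = 0.0457) and 2.12 (adjusted p = 0.0340, edgeR with Benjamini-Hochberg).

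Fkbp5 fell in both CT26-like (-0.97) and macrophage/monocyte-like cells (-2.38), and free tumour RNA might carry the fall into macrophages. The first test left this open: in sgControl the macrophage level was as low as 0.396 of the tumour level, which free RNA and a gene expressed less by macrophages both give. In sgControl macrophages the median tumour gene reached at most 0.117 of the share that Fkbp5 reached (71.9% and 39.6% of its tumour level), and the highest, Krt8, reached 15.6% of its tumour level in sgControl_2, which excludes free tumour RNA as the whole source. Lower output of the glucocorticoid receptor might lower Fkbp5 too: in macrophages the 15 other glucocorticoid-induced genes measured lay lower by camera, as predicted (p = 0.000579, 11 of 15 below 0, fry p = 0.00533), but not with an estimated correlation (p = 0.0667), so this stays open. In CT26-like cells 18 such genes had a camera p of 0.145, upward, with 2 up and 1 down, which decides nothing.

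The median log2 fold change of CT26-like genes differed between chromosomes, from -0.09 on chromosome 13 to 0.10 on chromosome 16. The SD of the chromosome medians was 0.0579 over 7717 genes, above the 95th percentile of 10000 gene shuffles (0.0171, permutation p = 0.0001, the smallest the shuffles can give). It was 0.0618 after a trend on gene length and expression was removed, which excludes that trend as the whole source. In macrophage/monocyte-like cells of the same tumours it was 0.0255 (95th percentile 0.0278, permutation p = 0.134), and for CT26-like minus macrophage/monocyte-like values 0.0592 (0.0273). These values are consistent with small copy number or clone differences between the injected cell populations, a hypothesis found on the same data, and genes near each other that respond together might add to it.

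Def8 was at 24934 to 30199 CPM in CT26-like and 2043 to 3642 CPM in macrophage/monocyte-like cells of all 4 libraries (log2 fold change -0.02 in CT26-like cells, not called by edgeR with Benjamini-Hochberg).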
